A study of Mus musculus with 5 samples.

How the data were processed

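Droplet libraries (10x Genomics 3' RNA) of live CD45+ cells came from C57BL/6 mice 4 days after subcutaneous injection of 5555 melanoma cells: a Ptgs+/+ line, a Ptgs-/- line that cannot make prostaglandins, and the Ptgs-/- line in mice depleted of NK cells with antibodies (anti-NK1.1 and anti-Asialo GM-1). A further library held CD45+ cells of CT26 tumours in BALB/c mice on day 12. The last library pooled, by hashtag, 3 conditions of bone marrow-derived DCs: untreated, with Ptgs+/+ and with Ptgs-/- 5555 cells. Per the labels' protocols 16000 to 18000 cells were loaded per 5555 library, with about 3.5% spiked-in cells, 25000 for CT26 and 30000 for the cultures.

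The deposited matrices hold 1 value per cell and gene, on the log2 scale. The submitters' processing notes name Cell Ranger 3.0.2, the mm10 genome and Partek, without order or settings. No header states the transformation, so the unit was tested on the values: 2 to the power of the deposited log2 value, minus 1, sums to the same CPM total in every cell with a gap of at most 0.00245% over all 3 matrices. The deposited values are therefore log2(CPM + 1) per cell. Over each matrix 99.9% of values above 0 (at least 99.46% in every cell) were whole multiples of what 1 UMI is worth (within 0.1 UMI plus 0.01%), which gave back the UMIs. In the 5555 matrix 15 symbols held parts of a UMI, 14 in CT26 and 16 in the cultures. For those no UMIs or intervals are given. The files hold no cell under 500 UMIs, and the highest mitochondrial share was 10.0%, in the 5555 libraries. The filters that produced this are not stated in the labels.

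Cells were joined to the authors' deposited annotation by barcode. Of 11872 cells in the 5555 matrix, 36 had no annotation and 18 carried 9 barcodes that more than 1 cell had, and all of these were left out, so 11818 were used. Total UMIs (median per cell) were 13341150 (3633.5) for Ptgs+/+, 24254769 (4562) for Ptgs-/-, 23193699 (5462) for NK-depleted Ptgs-/- and 39748621 (3822) for CT26. They were 35105381 (9709.5) for untreated BMDCs, 36870660 (8876.5) with Ptgs+/+ and 32883787 (8805) with Ptgs-/- cells.

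Cell types are the authors' own. The cells they call cDC3 (5555), actDC (CT26) and mDC (cultures) are written as CCR7+ DCs, and conventional DCs are cDC1s, cDC2s, their proliferating clusters and CCR7+ DCs. The 10 leading markers of the cluster that the authors call proliferating cDC2 (579 cultured cells) include none of the fixed cDC2 markers and include Cox6a2 (plasmacytoid DCs), Chil3 (monocytes) and Prtn3 (progenitors). No cells were clustered again and no doublet caller was run. Leaving out the 5% of cells with the most genes was planned in its place, but in cultures took out only 1.04% (with Ptgs+/+ cells) and 3.27% (untreated) of CCR7+ DCs. Free RNA was not subtracted. Classes with fewer than 30 cells in either group were not compared. Shares have exact Clopper-Pearson 95% intervals, ratios of shares intervals on the log scale, and both cover counting error only. For folds against a count of 0 UMIs, 3 counts were taken as the limit.

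Expression per class is the mean CPM over cells. Folds are differences of log2(mean + 5). Intervals of UMI ratios are exact conditional binomial 95% intervals of the summed UMIs, so a UMI ratio can differ from the fold of means. Where the median of all genes seen in at least 10% of cells moved by more than 0.1 log2, folds are relative to that median. Each of 19 lists of genes for functions was summarised by the median fold of its members in at least 5% of the cells of either group. Members are called higher or lower by size alone, at 1.5-fold. The percentile of a median refers to 10000 random lists of as many genes, matched on mean expression in 20 bins, and describes these libraries only. A further 24 lists of marker genes checked class identity.

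The groups, comparisons, lists, alternatives and the rule for named genes were chosen before the data were examined. The rule names the 2 to 4 members of a described list with the largest fold among those in at least 10% of cells, the 5 highest and 5 lowest genes per class and main comparison without receptor segments, haemoglobin, mitochondrial and ribosomal genes, and a short fixed set of DC, NK, T cell and prostaglandin genes. Genes of markers or doublet checks fall outside it. With 1 library per group no test between conditions, p-value or count of changed genes is given, and the hashtagged cultures share 1 library without replicate cultures.

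Alternatives were pseudocounts of 1 and 20, the difference of mean log2 values per cell, cells weighted by depth, list filters of none and 10%, centring or no centring, only cells with at least 500 genes, leaving out the cells with the most genes, DCs without a UMI of Cd3e, Ncr1, Cd79a, C1qa or S100a8, other denominators, and CCR7+ DCs defined by a Ccr7 and a Fscn1 UMI. Thinning to 2000 (tumours) or 5000 (cultures) UMIs per cell, and monocytes and macrophages without S100a8, were added after the data were seen.

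Calls were tested on simulated data with known folds for Ptgs-/- over Ptgs+/+. A true 2-fold difference was called on the right side for 90 to 94% of changed genes in cDC2s (6996 genes), 62 to 82% in CCR7+ DCs (5780 genes) and 96 to 98% in monocytes and macrophages (5810 genes). Unchanged genes passed 1.5-fold in 0.544%, 26.1% and 0% of cases, and unchanged lists fell outside the central 95% in 2.5%, 3.5% and 4.5%. The simulated cells of a group shared the same profile, so these rates cover counting error and not differences between cells. Unchanged lists were random genes ranked against random genes, which sets a low rate by construction. The list rates therefore do not carry over to lists of co-regulated genes. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.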

Results

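The 5555 melanoma libraries held 3262 CD45+ cells from Ptgs+/+ tumours, 4677 from Ptgs-/- tumours and 3879 from Ptgs-/- tumours of NK cell-depleted mice. The CT26 library held 8987 cells, and the cultured bone marrow-derived dendritic cells (BMDCs) 3344 untreated, 3884 with Ptgs+/+ and 3584 with Ptgs-/- 5555 cells. Each group is 1 library or 1 hashtagged condition, so every value below describes these libraries, and every interval covers counting error only. Numbers after gene names are log2 folds of the mean CPM over cells unless another unit is given. Total UMIs per group ran from 13341150 (Ptgs+/+ tumours) to 39748621 (CT26). Ptgs2, which encodes the inducible cyclooxygenase, averaged 1285 CPM over the cells of Ptgs+/+ tumours, 419 in Ptgs-/- tumours and 469 after NK depletion, and Ptgs1, the constitutive enzyme, averaged 3.27, 14.2 and 13.9. The deletion lies in the injected tumour cells, which a CD45 sort leaves out, so these levels are those of host leukocytes and check nothing about it.

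NK cells made up 4.20% of cells (counting interval 3.54-4.95) in Ptgs+/+ tumours and 10.9% (10.0-11.8) in Ptgs-/- tumours, 2.60-fold higher (2.16-3.12). T cells were 2.26-fold higher (1.72-2.97), at 2.02% and 4.58%. Neutrophils were 2.65-fold higher in Ptgs+/+ tumours, at 6.28% (5.48-7.17) against 2.37% (1.96-2.85). Neutrophils hold little RNA, the files hold no cell under 500 UMIs, and among cells with at least 500 genes (35.1% of neutrophils in Ptgs+/+ and 82.0% in Ptgs-/- tumours) the fold in Ptgs-/- over Ptgs+/+ tumours was 0.845 instead of 0.378. B cells (0.705% and 0.941%), conventional DCs (14.4% and 13.1%) and monocytes with macrophages (72.3% and 68.1%) differed less, and cDC1s, the cross-presenting subset, were 1.16% and 0.706% of cells. After NK depletion annotated NK cells were 1.16% (0.847-1.55), 9.40-fold below undepleted Ptgs-/- tumours, T cells 2.81%, neutrophils 1.96%, cDC1s 1.39% and monocytes with macrophages 80.1%. In that library the T cell gene Cd3e was seen in 24 of 45 cells annotated NK and in 47 of 109 annotated T. The T cell share leaves out the former, so part of its lower value may come from the annotation. Shares sum to the whole, so a higher share of 1 type lowers the others.

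**Figure D1:**
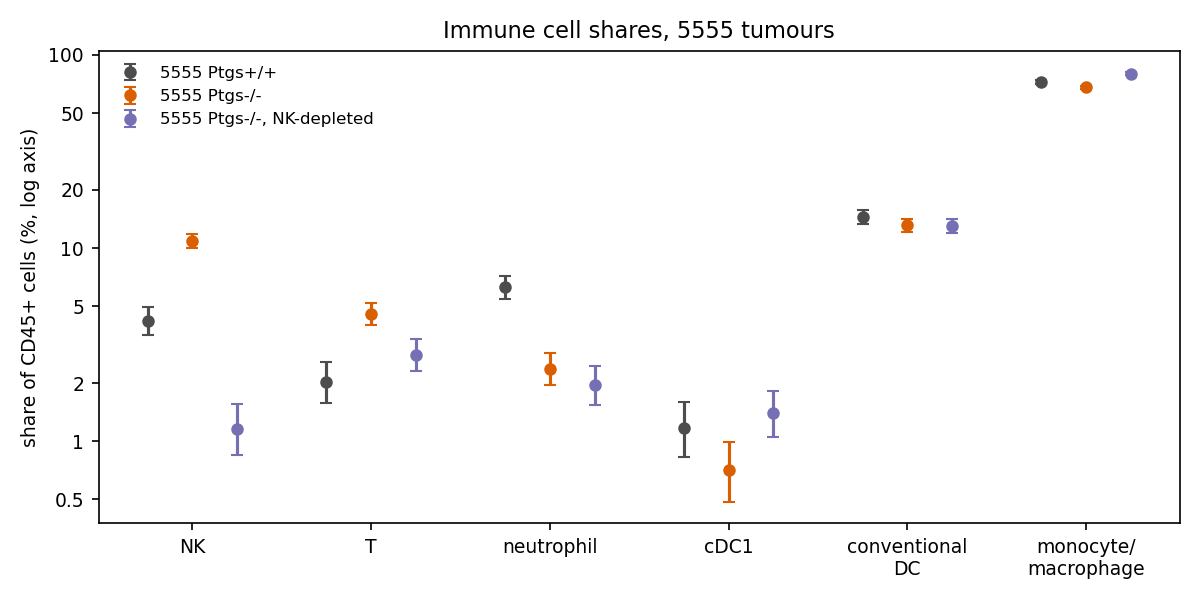
Share of CD45+ cells in percent (log axis) of 6 cell classes in the 3 libraries of 5555 tumours, with exact 95% counting intervals as bars and 1 library per point. Cells annotated NK, which in the depleted library largely lacked NK genes, stand at 4.20%, 10.9% and 1.16%, and conventional DCs lie close together in all 3 libraries.

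CCR7+ DCs, the mature migratory state, were 11.5% (8.73-14.7) of conventional DCs in Ptgs+/+ tumours, 9.45% (7.25-12.0) in Ptgs-/- tumours, 8.91% (6.57-11.7) after NK depletion and 11.9% (9.91-14.2) in CT26 tumours. These intervals overlap. Cells with both a Ccr7 and a Fscn1 UMI, counted without the annotation, were 8.92%, 8.63%, 7.52% and 10.5% of conventional DCs in the same order, at median depths of 5820, 7393, 7100 and 6025 UMIs. Thinned to 2000 UMIs per cell, which left out 8, 1, 3 and 2 cells, the shares were 6.70%, 7.50%, 6.57% and 8.21%, so that Ptgs-/- tumours stood above Ptgs+/+ tumours instead of below, with overlapping intervals (5.55-9.88 and 4.59-9.37). In monocytes and macrophages, which should lack the pair, at most 0.135% of cells had it at median depths of 3701 to 5491 UMIs.

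CCR7+ DCs of Ptgs-/- tumours carried more lymphocyte-attracting chemokine RNA and far less inflammatory cytokine RNA than those of Ptgs+/+ tumours. Ccl17, which attracts CCR4+ T cells, averaged 1393 against 5.61 CPM (773 against 2 UMIs, a UMI ratio of 300 with a counting interval of 82.8-2484). Ccl22, its neighbour with the same receptor, was higher by 1.60 and Ccl5 by 1.72 (5474 against 1653 CPM). Il15, the growth factor of NK cells and CD8 T cells, was higher by 2.38 (32 against 4 UMIs, ratio 6.21, 2.20-24.2), and the CXCR3 ligand Cxcl10 had 13 UMIs against 1 (ratio 10.1, 1.52-429). The list of T and NK cell-attracting genes had a median of 1.59, above 100% of 10000 random lists matched for level, with 7 higher, 1 lower and 4 within 1.5-fold. It stood at 0.85 as a difference of mean log2 values per cell and at 0.38 without the filter on detection. Il12b, the p40 chain that drives interferon-gamma in NK and T cells, was close to level at 0.15 as a mean over cells (395 against 356 CPM), though 198 against 109 UMIs gave a UMI ratio of 1.41 (1.11-1.80). Level too were Ccr7 at 0.09 and Fscn1 at -0.01.

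**Figure D2:**
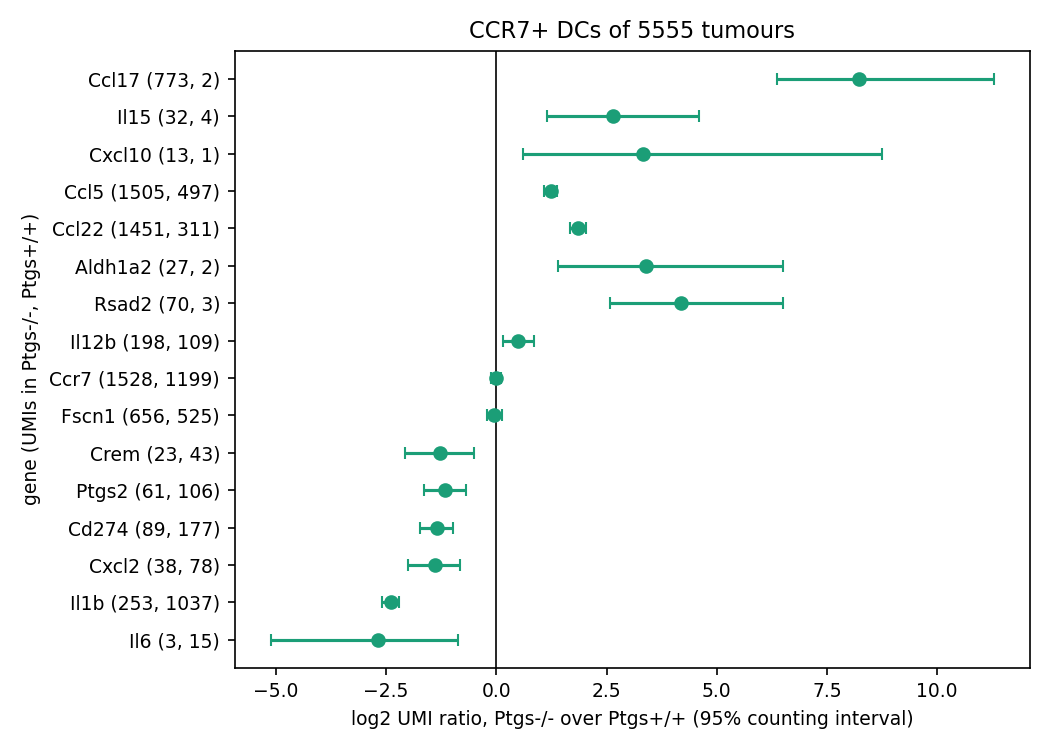
Log2 UMI ratio of 16 genes in CCR7+ DCs of Ptgs-/- over Ptgs+/+ 5555 tumours (points) with exact 95% counting intervals (bars) and UMIs of both libraries in brackets, a selection from the genes named in the text. Ccl17 lies farthest to the right, with 773 against 2 UMIs, and Il1b has the narrowest interval on the left side.

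In the same CCR7+ DCs the list of tumour-promoting inflammation had a median of -1.80 (percentile 0, 1 higher and 11 lower). Il1b averaged 544 against 3169 CPM (5.28-fold lower by UMIs, 4.59-6.08), Il6 had 3 UMIs against 15 (6.44-fold lower, 1.82-34.7), Osm was lower by log2 -2.19 and Cxcl2 by -1.91, while Tnf was higher at 2.02. Genes of the prostaglandin and cAMP list were lower (median -0.85, percentile 0.14, 6 of 9 lower), with the cAMP-responsive Crem at -1.20, Ptgs2 at -0.98 and Nr4a2 at -0.88. The list also holds the enzyme genes Ptgs1 and Ptgs2 and Nr4a genes, so it is no direct measure of prostaglandin signalling. Neutrophil marker genes were also lower in these cells (median -1.80, 0 higher and 4 lower), so neutrophil RNA is not excluded as part of this difference. The checkpoint ligand Cd274 averaged 222 against 636 CPM, Cd200 157 against 454 CPM and Socs1 stood at -1.78, but the retinoic acid enzyme Aldh1a2 had 27 UMIs against 2 (ratio 10.5, 2.64-91.0), so the regulatory list had a median of -0.06 (2 higher, 5 lower, 4 within).

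Co-stimulatory genes in CCR7+ DCs split between Icosl at 1.31 and Tnfsf9 at 1.15 and, on the other side, Cd86 at -1.11 and Tnfsf4, encoding OX40L, with 0 against 16 UMIs (at least 6.87-fold lower), for a list median of 0.57 (4 higher, 3 lower, 3 within). Of the genes induced by type I interferon, Rsad2 had 70 UMIs against 3 (ratio 18.1, 5.95-90.0) and Mx1 was higher at 2.05, yet Isg15 was lower at -1.19 and the list median was 0.21 (percentile 80.0). Interferon-gamma response genes had a median of 0.07, MHC class I genes -0.18 and MHC class II genes -0.39 (percentile 5.60), with H2-Eb1 at -0.88 and H2-Ab1 at -0.71. NF-kB pathway genes (-0.02) and DC migration genes (0.00) were level. Hypoxia and glycolysis genes were lower (-0.75, 8 of 11, Eno1 at -0.76) and the cholesterol list higher at 0.60 (0.43 with genes of 0 UMIs at their bound). The 5 highest and 5 lowest genes by the rule fixed beforehand added Kdr (35 against 0 UMIs, at least 9.06-fold), Vrk2 and Sod3 on the higher side and the lipid carrier Fabp4 (34.3 against 538 CPM), Myo10, Casp6 and Cystm1 on the lower side. With 58 and 54 cells, a simulated gene with no difference passed 1.5-fold by counting alone in 26.1% of cases, so single genes with few UMIs carry little weight.

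The 523 cDC2s of Ptgs-/- tumours also held Ccl17 RNA that the 379 of Ptgs+/+ tumours lacked, with 948 against 0 UMIs (at least 192-fold, in 16.8% of cells). Lpl, which hydrolyses triglycerides, had 1336 UMIs against 2 (ratio 405, 112-3350), Arg1, which degrades arginine, 1058 against 2 (ratio 321, 88.6-2654), the eosinophil-associated ribonuclease Ear2 stood at 5.21 and the monocyte attractant Ccl7 at 4.01. Genes of alternative macrophage activation had a median of 1.90 (percentile 100, 5 higher, 1 lower, 1 within; 1.25 by mean log2 values, 1.39 with a pseudocount of 20 and 0.98 without the filter), including Fn1 at 3.73, Mrc1 at 1.90 and Retnla (109 against 0 UMIs, at least 22.0-fold). Macrophage markers as a group were higher too, at 1.24 (8 higher, 0 lower), and monocyte markers at 0.62, against 0.12 for cDC2 markers. Cell-cycle genes were higher (median 1.63, 10 of 11), with Mki67 at 2.11 and Top2a at 2.01.

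Among the other cDC2 genes, the T and NK list stood at 0.65 (percentile 100, but -0.46 over the members in at least 10% of cells) with Ebi3 at 0.75 and Ccl4 lower at -0.68 (0.26 as a difference of mean log2 values per cell), and type I interferon genes at 0.56 (7 higher, 0 lower, 7 within) with Rsad2 at 2.03 and Ifit1 at 1.03. The GTPases Gbp2 at 1.53, Gbp4 at 1.36 and Gbp3 at 1.22 were higher although the interferon-gamma median was 0.15. Prostaglandin and cAMP genes were lower (-0.65, percentile 0.01), with Pde4b at -1.15, Ptgs2 at -1.13 and Crem at -0.98, and tumour-promoting inflammation had a median of -0.38 with Il1b at -1.02 (1774 against 3608 CPM) and Ccl2 higher at 3.59. Tnfsf4 had 2 UMIs against 134 and Cd86 stood at -1.55, Cd80 at -1.06 and Cd274 at -1.65. MHC class I (-0.03) and class II (-0.15) genes were level. The lowest genes were Ifitm1, an interferon-induced membrane protein (-4.62, 202 against 5064 CPM), Dmkn at -3.55, B3gnt5 at -2.84 and the protease inhibitor Timp1 at -2.65.

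In cDC1s (33 against 38 cells) Ifitm1 was again the lowest gene, 74.1 against 3699 CPM (53.2-fold lower by UMIs, 34.2-87.6). Xcr1, the receptor through which cDC1s follow NK and T cell-derived XCL1, was higher at 2.89 and Clec9a, which senses dead cells, at 1.43. Both were among the leading markers of the cDC1 annotation, so a difference in the purity of that class is not excluded. Cell-cycle genes were higher with a median of 3.26 (2.56 with genes of 0 UMIs at their bound), including Top2a (61 against 0 UMIs, at least 16.3-fold) and Mki67 (49 against 0, at least 13.1-fold). Type I interferon genes had a median of 0.84 (percentile 98.8, Ifi44 at 2.39, Isg15 at 1.36), while Cd274 had 2 UMIs against 14 and the regulatory list stood at -2.06 (-1.60 at the bound). The T and NK list was near level at 0.16, with Ccl3 at -1.41 and Ccl4 at -1.24. Il1b averaged 1344 against 3799 CPM and Cxcl2 stood at -1.38, yet the tumour-promoting list was higher at 1.16 (5 higher, 2 lower, 1 within), mostly through the neutrophil genes S100a8 (138 against 0 UMIs) and S100a9 (200 against 2 UMIs), chosen after their values were seen. Without cDC1s holding a UMI of another lineage it stood at -0.35.

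Monocytes and macrophages of Ptgs-/- tumours (3184 against 2360 cells) had more interferon-induced and less inflammatory RNA. Type I interferon genes had a median of 1.03 (percentile 100, 11 higher, 0 lower, 3 within), led by Rsad2 at 1.79 (264 against 72.8 CPM), Ifit2 at 1.60, Cmpk2 at 1.45 and Ifit3 at 1.30. Interferon-gamma genes stood at 0.50 (5 higher, 0 lower, 7 within, Gbp2 at 1.28), MHC class II genes at 0.51, MHC class I genes at 0.24 and Cxcl10 at 1.31. Tumour-promoting inflammation had a median of -1.17 (percentile 0, 1 higher, 8 lower, 3 within), with the neutrophil attractant Cxcl3 at -3.55 (23.3 against 327 CPM), Ptgs2 at -1.62, Trem1 at -1.60, Il1b at -1.27 (1478 against 3581 CPM) and Cxcl2 at -0.93. Ccl2, which recruits monocytes, was higher at 2.12. Neutrophil markers were lower in this class (median -2.65, percentile 0), and the lowest genes, Ifitm1 at -6.36, Mmp9 at -5.07, Slpi at -4.45, Ramp3 at -3.64 and Il1r2 at -3.61, include products of neutrophils, which were more frequent in the Ptgs+/+ library, and Slpi, a marker of TAM 2, which was 28.7% of the class in Ptgs+/+ and 7.54% in Ptgs-/- tumours. Inside TAM 1, Mmp9 stood at -6.22 and Il1r2 at -3.88.

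Alternative activation genes of monocytes and macrophages were higher at 0.84 (5 higher, 1 lower, 3 within), with Retnla at 4.05, Folr2 at 2.16, Arg1 at 1.55 and Chil3 lower at -1.33. The lysosome and phagocytosis list stood at 0.55 with the lipid receptor Cd36 at 2.60, Axl at 1.76 and Gpnmb at 1.40, and Lpl was the highest gene at 4.56 (944 against 35.3 CPM), followed by Gatm at 3.11 and Pmp22 at 2.91. Cd83 was higher at 1.71, the prostaglandin E2 receptor Ptger4 averaged 77.8 against 24.2 CPM, and Cd80 stood at -1.43, Cd86 at -0.98 and Pde4b at -1.42. The class is a mixture whose clusters differ in size: TAM 2 (678 cells) and TAM 1 (609) were largest in Ptgs+/+ tumours and TAM 1 (932) and Monocytes 1 (695) in Ptgs-/- tumours. Within TAM 1, type I interferon genes had a median of 0.47, tumour-promoting inflammation -0.93 and alternative activation 0.89. Within Monocytes 1 the same lists stood at 0.98, -1.34 and -0.58, so the interferon and inflammation directions held in both and alternative activation did not.

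NK cells of Ptgs-/- tumours were a larger share of cells, and their effector RNA was close to level as a mean over cells but not as a difference of mean log2 values per cell. The cytotoxic list had a median of 0.11 by the former (percentile 83.9, 2 higher, 2 lower, 8 within) and 0.79 by the latter, with Ifng at 0.03, Gzma at -0.06, Xcl1 at -0.04, Prf1 at 0.42, Gzmb at 0.62, Fasl at 1.16 and Nkg7 at -0.59. Gzmc, a granzyme of strongly activated cells, was the lowest gene at -5.40 (22.9 against 1171 CPM, 64.2-fold lower by UMIs, 45.6-93.1). Its 542 UMIs in Ptgs+/+ tumours lay in only 17 of 137 NK cells (12.4%). The interval does not cover such differences between cells. Cell-cycle genes were higher at 0.64 (4 of 6) and checkpoint genes lower at -0.42. Tumour-promoting genes such as S100a9 at -4.06, Cxcl2 at -3.20, Ptgs2 at -2.47 and Il1b at -2.27 were lower, as were neutrophil markers (median -2.54, 0 higher, 7 lower), in 510 against 137 cells.

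T cells, annotated by the authors as 1 class so that CD8 T cells could not be taken alone, had higher levels of interferon-induced genes in Ptgs-/- tumours (214 against 66 cells). Type I interferon genes had a median of 1.65 (7 higher, 0 lower, 1 within, Isg15 at 1.06), interferon-gamma genes 0.51 (percentile 99.2, Gbp4 at 1.12) and MHC class II genes 1.17 with Cd74 at 1.28. Free RNA was not subtracted and no doublet caller was run. RNA of DCs and macrophages is therefore not excluded as a source of these values, those of MHC class II genes included. Ifng itself had 34 UMIs against 1 (ratio 8.08, 1.36-328). Pdcd1, the exhaustion-associated PD-1 receptor, was lower at -2.18, Gzmb at -1.34 and Crem at -1.16, with the cytotoxic list at 0.49 and the checkpoint list at -0.31. In Ptgs+/+ and Ptgs-/- tumours Cd3e was seen in 53.0% and 51.4% of this class and Il1rl1 in 18.2% and 27.1%, with overlapping intervals. Gata3 was seen in 33.3% (22.2-46.0) and 56.1% (49.1-62.8), intervals that do not overlap. A different mixture of cells could give part of these values and of the higher share.

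NK depletion of mice with Ptgs-/- tumours went with lower interferon-gamma response RNA in monocytes, macrophages, cDC2s and T cells. In monocytes and macrophages (3108 against 3184 cells) interferon-gamma genes had a median of -0.28 (percentile 0, 0 higher, 3 lower, 9 within, Gbp2 at -0.82, Cd274 at -0.46) and type I genes -0.19 (0 higher, 0 lower, 14 within, and 0.08 as a difference of mean log2 values per cell). Here the pooled class hides larger differences, since Monocytes 1 (1108 cells after depletion, 695 before) stood at -0.80 for interferon-gamma genes (10 lower, 0 higher) and -0.43 for type I genes, and TAM 1 at -0.36 and -0.64. In cDC2s (406 against 523) the medians were -0.30 (Gbp4 at -1.41, Gbp2 at -0.92, Gbp3 at -0.70) and -0.40. T cells (109 against 214) had type I genes at -1.06 (0 higher, 6 lower, 2 within, Isg15 at -1.28) and interferon-gamma genes at -0.71 (0 higher, 7 lower, Psmb9 at -0.80).

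Effector genes of T cells were lower in the NK-depleted library, and direct loss of T cells to the depleting antibodies was not tested. Ccl5 had 5 UMIs against 295 (33.0-fold lower, 14.0-102), Nkg7 stood at -3.01, Ifng had 4 UMIs against 34, Cd8a stood at -1.34 with 6 against 24 UMIs (in 2.75%, 0.571-7.83, against 5.14%, 2.59-9.01, of cells), and the naive and central memory receptor Ccr7 was higher at 2.23 (362 against 73.2 CPM), next to Actn1 at 2.89 and Cd24a at 2.87. The cytotoxic list had a median of -1.06 (2 higher, 5 lower, 1 within), with Pdcd1 higher at 1.58. A different mixture of cells could give such values. In the T cell class Gzma was seen in 10 of 214 cells before and 0 of 109 after depletion, Ncr1 in 3 and 0 and Prf1 in 11 and 3, with overlapping intervals of these shares. Areg was seen in 15.4% (10.9-20.97) of cells before and 29.4% (21.02-38.8) after depletion, intervals that do not overlap. Il1rl1 was seen in 27.1% and 39.4%, Gata3 in 56.1% and 59.6% and Cd3e in 51.4% and 43.1%, with overlapping intervals. After depletion some Cd3e+ cells were annotated NK.

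**Figure D3:**
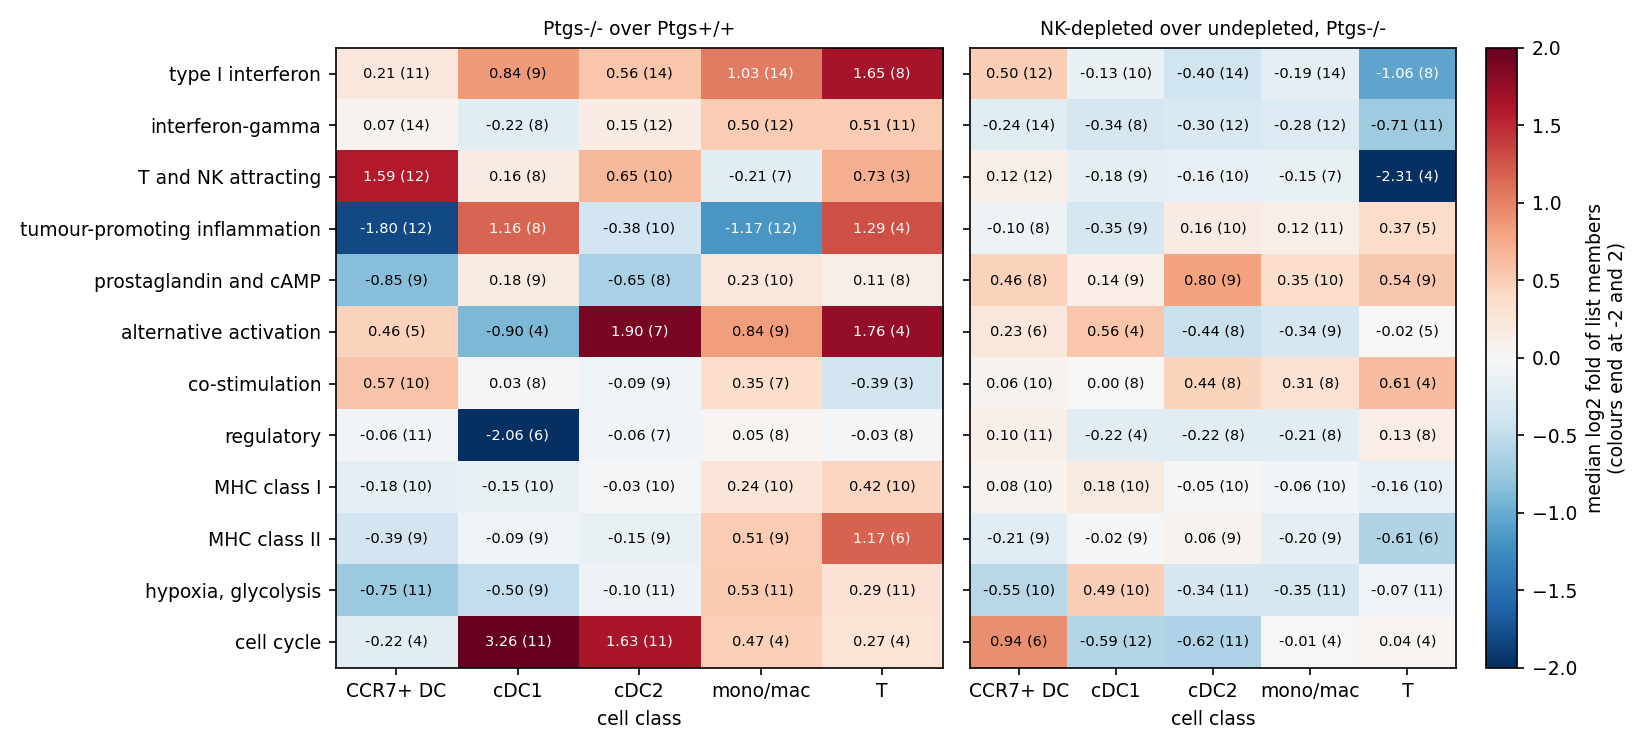
Median log2 fold of 12 gene lists (lines) in 5 cell classes (columns) for Ptgs-/- over Ptgs+/+ tumours (left) and for NK-depleted over undepleted mice with Ptgs-/- tumours (right), with the number of measured members in brackets and colours that end at -2 and 2. Type I interferon genes stand at 1.03 in monocytes and macrophages and 1.65 in T cells on the left, and at -0.19 and -1.06 on the right.

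CCR7+ DCs after NK depletion (45 against 58 cells) had Ccl17 at -1.29 (567 against 1393 CPM), Ccl22 at -0.15, Il12b at 0.45, Il15 at -0.78, Il15ra at 1.00 and Cxcl10 at 2.00 (20 against 13 UMIs, ratio 2.09, 0.987-4.56, and -0.13 by mean log2 values), so the T and NK list was near level at 0.12 (3 higher, 3 lower, 6 within). Interferon-gamma genes had a median of -0.24 and type I genes 0.50 (0.42 at the bound), with Irf7 at 1.59 against Isg15 at -0.89. Co-stimulatory genes (0.06) and regulatory genes (0.10) were level. The glycolysis gene Eno1 had 2 UMIs against 53 and the hypoxia list stood at -0.55. In cDC2s the prostaglandin and cAMP list was higher at 0.80 (7 higher, 0 lower, 2 within, Nr4a1 at 1.34, Ptgs2 at 1.15, Nr4a3 at 0.98) next to the dissociation-stress list at 0.55, NF-kB genes at 0.48 (Tnfaip3 at 1.16, Nfkbia at 1.11) and co-stimulatory genes at 0.44 (Cd83 at 1.29, Pvr at 0.79), while cell-cycle genes (-0.62, Mki67 at -1.14) and alternative activation genes (-0.44, Arg1 at -1.72, Fn1 at -0.77) were lower. The platelet factor Pf4 was the lowest gene of cDC2s (-2.74) and of monocytes and macrophages (-1.80, 624 against 2192 CPM), where Chil3 was highest at 1.59. TAM 1, with Pf4 as its top marker, was 15.5% of that class after depletion against 29.3% before, and Monocytes 2, with Chil3 among its markers, 14.4% against 8.07%, while inside TAM 1 Pf4 averaged 2036 against 4282 CPM and inside Monocytes 2 Chil3 stood at 0.81. Macrophage markers were lower in both classes, at -0.75 and -0.49.

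The cells annotated NK in the depleted library largely lacked NK genes. None of the 45 had an Ncr1, Gzma, Prf1, Klra8 or Eomes UMI (0 of 45 cells, exact upper bound 7.87% of cells with a UMI, at a median depth of 2518 UMIs) and 2 had Klrb1c, which encodes NK1.1, whereas 48.6% of NK cells in undepleted Ptgs-/- tumours had Ncr1 and 73.3% Klrb1c, at a median of 2095.5 UMIs. Instead 53.3% had the T cell receptor subunit Cd3e, 51.1% Cd4, 31.1% the IL-33 receptor Il1rl1 and 9 of the 45 the regulatory T cell factor Foxp3. No expression of NK cells was therefore compared for the depleted mice, and the share of 1.16% overstates the NK cells left. The T cell share of that library leaves out the Cd3e+ cells annotated NK.

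CCR7+ DCs held more co-stimulatory RNA than cDC1s and cDC2s in the 4 tumour libraries and in untreated cultures. Because the median of all genes was lower in CCR7+ DCs by log2 0.12 to 0.36, the folds of this paragraph are relative to it, and genes such as Ccr7, Fscn1 and Ccl22 that define the class are no result. In CT26 tumours co-stimulatory genes had a median of 2.53 over cDC1s (10 of 10 higher) and 1.68 over cDC2s, with Cd40 at 3.37 and 2.20, Cd80 at 3.15 over cDC1s and Cd83 at 1.79 over cDC2s. Il12b stood at 6.44 (778 against 6.01 CPM) and 5.26, and Ccl5 at 7.29 (11316 against 86.0 CPM) and 5.33. Il12b was among the leading markers of CCR7+ DCs in every matrix, so its folds over other DCs may partly restate the annotation. Inhibitory genes were higher as well, with Cd274 at 3.95 and 3.30, Pdcd1lg2 at 3.98 and 3.55 and Cd200 at 4.44 and 5.59. MHC class I genes stood at 1.45 and 1.44 (H2-K1 at 2.34 and 1.78) and MHC class II genes at -1.21 and -1.38, with the peptide-loading subunit H2-DMb1 at -2.64 and -3.33.

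In the 5555 tumours and the cultures the co-stimulatory list stood at 1.59 over cDC1s and 1.38 over cDC2s for Ptgs+/+ tumours, 2.66 and 1.95 for Ptgs-/- tumours, 2.59 and 1.47 after NK depletion, and 1.74 and 1.67 in untreated BMDCs. In Ptgs+/+ tumours Cd40 was higher at 4.15 and 2.64 and Cd274 at 3.35 and 3.33, and Il12b had 109 UMIs against 0 in both cDC1s and cDC2s. MHC class II genes stood at -0.10 and -0.34 there and H2-DMb1 at -2.32 and -2.65. Tumour-promoting inflammation relative to cDC2s was near level in Ptgs+/+ tumours at -0.03 but lower at -1.37 in Ptgs-/- tumours, -1.06 after NK depletion and -0.82 in CT26 tumours (0.00 there by mean log2 values). The filter on detection kept 12 members in Ptgs+/+, 9 in Ptgs-/- and 11 in CT26 tumours, so these medians do not cover the same genes. The cDC2s they refer to differed between tumours too. Type I interferon genes were higher than in cDC1s at 0.97 in Ptgs+/+ tumours and lower at -1.13 in untreated BMDCs.

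CCR7+ DCs were 6.81% (5.95-7.74) of conventional DCs in untreated cultures, 28.8% (27.3-30.3) with Ptgs+/+ 5555 cells, 4.23-fold higher (3.68-4.86), and 14.6% (13.4-15.8) with Ptgs-/- cells, 2.14-fold higher. Cells with both a Ccr7 and a Fscn1 UMI were 5.53%, 19.1% and 8.65%, at median depths of 10053.5, 9047.5 and 9127 UMIs, and 3.52%, 14.5% and 5.75% after thinning to 5000 UMIs, which left out 192, 262 and 247 cells. At most 0.321% of plasmacytoid DCs had both. Ccr7 itself was higher in cDC1s and cDC2s with tumour cells, so cells near the border of the annotation are not excluded as part of the higher share. Proliferating cells were 45.3% of cDC1s untreated, 34.3% with Ptgs+/+ and 39.3% with Ptgs-/- cells, but 17.1%, 19.5% and 24.8% of cDC2s in the same order, and plasmacytoid DCs 5.98%, 5.15% and 8.71% of all cells. The cluster annotated as proliferating cDC2s had no fixed cDC2 marker among its leading markers, which limits its share.

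**Figure D4:**
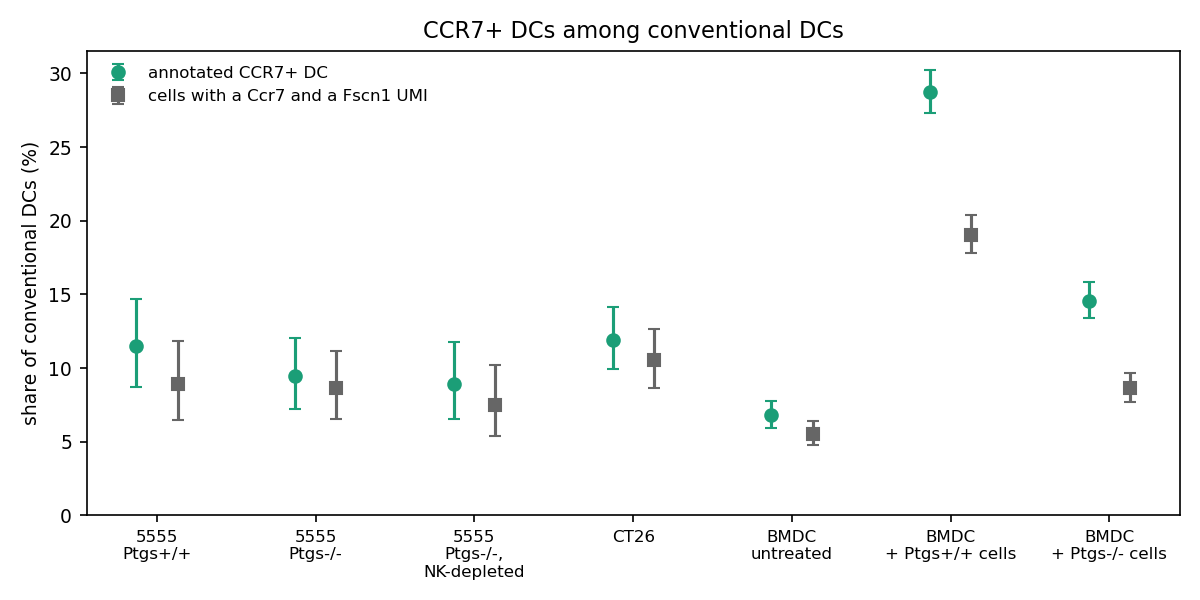
Share of conventional DCs in percent that the authors annotated as CCR7+ DCs (circles) or that hold both a Ccr7 and a Fscn1 UMI (squares), in 4 tumour libraries and 3 culture conditions, with exact 95% counting intervals as bars. The tumours lie between 8.91% and 11.9% annotated cells, and cultures with Ptgs+/+ cells reach 28.8%.

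CCR7+ DCs of treated cultures carried more co-stimulatory and Il12b RNA than the untreated ones. The median of all genes was lower in treated cells by log2 0.12 to 0.28, and folds against untreated cells are relative to it. With Ptgs+/+ cells (1060 against 214 cells) Il12b was highest at 2.52 (202 against 38.7 CPM), followed by Il1b at 2.40, Plek2 at 2.17, Apoc2 at 2.03 and Traf4 at 1.89. Co-stimulatory genes stood at 1.05 (percentile 100, 7 higher, 1 lower, 2 within), with Cd70 at 1.59, Cd40 at 1.35, Tnfsf9 at 1.21 and Pvr at 1.20, NF-kB genes at 0.63, prostaglandin and cAMP genes at 0.57, the T and NK list at 0.37 (4 higher, 2 lower, 4 within) and tumour-promoting genes at 0.33 (3 higher, 2 lower, 1 within). Isg15 was higher at 1.82, but type I interferon genes as a list were level at 0.04 and interferon-gamma genes lower at -0.37 (Gbp2 at -1.45, 0.05 without the filter on detection). The inhibitory genes Il4i1 at 1.07, Cd274 at 0.92 and Cd200 at 0.79 were higher, while the regulatory list they belong to had a median of 0.28 (5 higher, 1 lower, 5 within). Cell-cycle genes were lower at -0.64, and the lowest genes were Naaa at -2.14, Egr1 at -2.03, Ccr2 at -2.01, Sept3 at -1.99 and S100a8 at -1.95 (0.03 by mean log2 values). Naaa and Sept3 were among the leading markers of cDC1s in CT26 tumours. Fewer cDC1-like cells in the class are therefore not excluded as part of these differences.

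With Ptgs-/- cells (477 against 214) Il12b was again highest at 2.70 (239 against 38.7 CPM), and co-stimulatory genes stood at 0.64 (6 higher, 0 lower, 4 within, Tnfsf9 at 1.29, Cd70 at 0.87, Cd83 at 0.78), prostaglandin and cAMP genes at 0.82 and the T and NK list at 0.45 with Ccl5 at 0.89. Compared directly, CCR7+ DCs with Ptgs-/- cells had less Il1b than those with Ptgs+/+ cells (-1.80, 159 against 566 CPM), and co-stimulatory genes at -0.25 (percentile 0.10, 0 higher, 3 lower, 7 within), with Cd70 at -0.67, Pvr at -0.62 and Cd40 at -0.62. Ccl5 at 0.55, Ccl22 at -0.47 and Il12b at 0.23 all lay within 1.5-fold. Rhoh at 1.63, Epsti1 at 1.19 and Atf3 at 1.18 were the highest genes, Apol7c at -1.22 and Mcemp1 at -1.13 among the lowest.

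Other cultured DCs also differed between conditions. In cDC1s with Ptgs+/+ cells (1111 against 1165) prostaglandin and cAMP genes were higher at 1.62 (7 higher, 0 lower, 2 within) next to the dissociation-stress list at 0.58, with Crem at 2.38, Nr4a2 at 2.29, Ptgs1 at 1.67 and Pde4b at 1.62, and Cd83 stood at 2.01, Il1b at 2.82, Ccl4 at 2.55, Cd274 at 2.32, Ccr7 at 1.69 and Ramp3 at 3.18. Since Ccr7 marks CCR7+ DCs, cells near the border of that annotation are not excluded as part of these differences. With Ptgs-/- cells the prostaglandin list of cDC1s was above untreated cells too, but less so, at 0.75 (Crem at 2.02, Nr4a2 at 1.87). Compared directly with Ptgs+/+ cells it was lower at -0.29 (percentile 0), with Ccr7 at -1.11, Ptgs1 at -0.95 and Cd274 at -0.74. In cDC2s the prostaglandin list stood at 1.06 with Ptgs+/+ and 1.00 with Ptgs-/- cells, the dissociation-stress list at 0.86 and 0.40, and NF-kB genes at -0.34 with Ptgs-/- over Ptgs+/+ cells, with 12 of 12 within 1.5-fold. The heat shock gene Hspa1a was the highest gene of cDC2s with Ptgs-/- cells at 3.46, against 2.25 with Ptgs+/+ cells.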

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

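The tests below of CCR7+ DCs per cDC2 and per plasmacytoid DC, of the UMIs of CCR7+ DCs, of monocyte and macrophage RNA in cDC2s, and of free RNA and of doublets for Cxcl2, Ptgs2 and Il1b in NK cells (1 test per gene after a pooled one at 62.9%) were chosen only after the result was seen, as was the comparison of S100a9 with random scatter. A signal appeared in cells that no annotation covers: the 36 cells of the 5555 matrix without one averaged 960.0 CPM of the kinase gene Prkg2 against 3.01 in annotated cells. All 36 had Prkg2, Sparc and Hmga2, their median depth was 13892.2 UMIs, and only 5 had the leukocyte gene Ptprc. The melanocyte genes Pmel and Dct had 0 UMIs, and the origin of the cells was not tested. The protocols name about 3.5% spiked-in cells in the 5555 libraries, and no label says whether the 36 are among them.

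Cultured DCs with Ptgs+/+ tumour cells held 4.23-fold more CCR7+ DCs among conventional DCs than untreated ones. A difference in depth is argued against, since the share of cells with a Ccr7 and a Fscn1 UMI was 4.12-fold higher (3.36-5.06) after every cell was thinned to 5000 UMIs. Doublets as most of these cells are argued against, since the median UMIs of CCR7+ DCs were 85.7% (82.9-88.5) of those of cDC1s, the other conventional DC class with the fewest, and a loss of other conventional DCs that spares plasmacytoid DCs by 4.95-fold more CCR7+ DCs per plasmacytoid DC (3.88-6.33). A smaller part of doublets cannot be told apart, because leaving out the 5% of cells with the most genes (ratio 4.32, 3.75-4.98) took out only 1.04% of these CCR7+ DCs, nor can a loss of all other DCs alike, which would raise the ratio of CCR7+ DCs per cDC2 (4.38, 3.66-5.24) as much as the share. A response of the cultured DCs to the tumour cells and a difference between hashtagged cultures, 1 per condition, stay open too.

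In cDC2s of Ptgs-/- tumours Ccl17, Lpl, Ear2, Arg1 and Ccl7 were far higher. RNA or doublets of monocytes and macrophages are argued against as the source of Ccl17, whose cDC2 level was 398% of that in the cluster with the most (Mono Mac). CCR7+ DCs, which averaged more Ccl17 than cDC2s, were not tested as a source. Their RNA, doublets with them and cells near the border of that annotation are not excluded. Cells with a UMI of Cd3e, Ncr1, Cd79a, C1qa or S100a8 are argued against as the source by a median of 4.97 without them (5.21 in all cDC2s). None of these genes is among the leading markers of Mono Mac, so this filter could not exclude cells of that cluster. For Ear2 such RNA cannot be told apart from expression by the cells, because it reached 35.2% of its Mono Mac level and other leading markers of that cluster from 0.501% (Retnla) to 43.4% (Fgfr1), nor for Lpl, Arg1 and Ccl7, at 27.5%, 14.0% and 12.0% of the level of the whole class against 45.6% for C1qb and 8.92% for Apoe. A single test over all 5 genes, run earlier, was undecided too (45.6% against a median of 27.5%). A larger part of monocyte-derived cells cannot be told apart either, with monocyte markers at 0.62, macrophage markers higher as a group and cDC2 markers at 0.12, so a changed cDC2 programme and a changed mixture may both contribute.

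In NK cells S100a9, Cxcl2, Ptgs2 and Il1b were lower in Ptgs-/- tumours. Free RNA is argued against as the whole source, since T cells of the Ptgs+/+ library had 0 S100a9 UMIs, with an upper bound of 33.5 CPM over pooled UMIs, against 869 (766-982) in NK cells. Doublets with myeloid cells match the values for Ptgs2 and Il1b: the 7 of 137 NK cells with the most S100a9, which held 7.04% of all UMIs, held 81.3% (70.7-89.4) and 69.9% (63.9-75.5) of their UMIs, against 0.185% for Gzmc. Of the 7 cells 42.9% had Nkg7 (89.1% of the class), and 57.1% each had Gzma (86.1%), Prf1 (65.7%), Klrb1c (62.8%) and Ncr1 (48.9%). Myeloid cells annotated NK can therefore not be told apart from doublets. Doublets cannot be told apart from expression by few cells for Cxcl2, of which the same 7 cells held 42.2% (34.3-50.4), around the limit of 50%, nor for S100a9 itself, whose UMIs lay in only 15 cells, so that the 89.1% (84.6-92.6) held by the top 7 compares with 55.8% under random scatter over those 15. Without cells holding S100a9 in either library, Cxcl2 stood at -0.85, Ptgs2 at -1.23 and Il1b at -1.21. Part of the difference in Ptgs2 and Il1b may thus come from a few doublets or myeloid cells annotated NK, and the rest stays open.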

How the results depend on the processing

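No paired analysis was possible because each group is 1 library or 1 hashtagged condition, and other cluster resolutions were not run because the authors' annotation was used. Thinned CCR7+ DC shares and monocytes and macrophages without S100a8 were chosen only after the data were seen. The direction held in 1813 of 1820 alternative values of genes, 854 of 861 of lists and 46 of 47 of share ratios whose counting interval excluded no difference. A changed pseudocount cannot reverse the fold of a gene that is not centred, and many genes were named for their large folds. Part of these counts was therefore fixed in advance, and they do not measure robustness.

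Among cells with at least 500 genes the neutrophil share ratio moved to 0.845 (from 0.378) for Ptgs-/- over Ptgs+/+ and to 0.596 (from 0.826) for NK-depleted over undepleted mice, because that limit kept 35.1%, 82.0% and 59.2% of neutrophils in Ptgs+/+, Ptgs-/- and depleted libraries. The ratio of monocytes and macrophages was 0.908 with that limit (from 0.941), 0.903 without neutrophils in the denominator and 1.01, the other direction, without NK cells, which follows from the higher NK share. After depletion it was 1.06 (from 1.18) without NK cells. NK cells defined by Ncr1 gave a ratio of 0 after depletion (from 0.106), since 0 cells of that library met the definition.

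Defined by a Ccr7 and a Fscn1 UMI, CCR7+ DCs were 5.53%, 19.1% and 8.65% of cultured conventional DCs (untreated, Ptgs+/+, Ptgs-/-), with ratios of 3.44 and 1.56 over untreated cells and 0.454 for Ptgs-/- over Ptgs+/+ cells. After thinning they were 3.52%, 14.5% and 5.75% (ratios 1.63 for Ptgs-/- over untreated and 0.396 over Ptgs+/+ cells), and 6.70%, 7.50%, 6.57% and 8.21% in Ptgs+/+, Ptgs-/-, NK-depleted and CT26 tumours, since fewer UMIs detect fewer cells. Thinning turned the order of Ptgs-/- and Ptgs+/+ tumours around (9.45% and 11.5% annotated), within overlapping intervals.

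The difference of mean log2 values per cell, which weights low expressers more, moved most values. For Ptgs-/- over Ptgs+/+ tumours it gave 0.85 (T and NK list) and -0.88 (tumour-promoting) in CCR7+ DCs, 1.25 (alternative activation) in cDC2s, 0.67 (type I interferon) and -0.74 (tumour-promoting) in monocytes and macrophages, and 0.79 (cytotoxic) in NK cells. It gave 1.15 for prostaglandin genes in cDC2s after depletion, and for cultured co-stimulation 1.20 with Ptgs+/+ over untreated and -0.57 with Ptgs-/- over Ptgs+/+ cells. It reversed Ccl4 in cDC2s (0.26), type I interferon genes in monocytes and macrophages after depletion (0.0820), Cxcl10 in CCR7+ DCs after depletion (-0.13), tumour-promoting genes of CCR7+ DCs over cDC2s in CT26 (0.00220) and S100a8 in cultured CCR7+ DCs (0.0251).

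A pseudocount of 20 gave -1.13 for tumour-promoting genes in CCR7+ DCs, 1.39 for alternative activation in cDC2s, 0.74 for type I interferon genes in monocytes and macrophages, and for co-stimulation 1.75 and 1.17 over cDC1s and cDC2s in CT26 and 0.88 in cultures. A pseudocount of 1 gave 3.03 over cDC1s in CT26 and 1.20 in cultures. Without the filter on members the T and NK list in CCR7+ DCs stood at 0.38, alternative activation in cDC2s at 0.98, tumour-promoting genes in monocytes and macrophages at -0.68 and, reversed, interferon-gamma genes in cultured CCR7+ DCs at 0.0540, since unseen members stand near 0. With members in at least 10% of cells, monocytes and macrophages stood at -0.998, cultured co-stimulation with Ptgs-/- over Ptgs+/+ cells at -0.33 and, reversed, the T and NK list in cDC2s at -0.46 and tumour-promoting genes in cDC1s at -0.58. Centring gave -1.21 for tumour-promoting genes in monocytes and macrophages, and no centring 1.32 for CT26 co-stimulation over cDC2s and 0.78 in cultures. Without S100a8 UMIs the tumour-promoting list of monocytes and macrophages stood at -0.95. Leaving out DCs with a UMI of another lineage reversed tumour-promoting genes in cDC1s (-0.35) and S100a8 in cultured CCR7+ DCs (0.28), as it removes every cell with S100a8. For the other changes the cause was not tested.

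Of all alternative values, 1505 of 1903 for genes, 874 of 1059 for lists and 73 of 94 for shares stayed within their counting interval. Depth limits single genes in the small classes: CCR7+ DCs and cDC1s had 33 to 58 cells per 5555 library, and neutrophils 842 (Ptgs+/+), 1156 (Ptgs-/-) and 965.5 (depleted) UMIs per cell at the median.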

Other observations

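The contrast of NK-depleted with Ptgs+/+ tumours, the cluster values beside the hypoxia list and the genes of the proliferating CT26 cells were chosen only after the data were seen, and no further hypothesis was tested in this part. Neutrophils of Ptgs-/- tumours (111 against 205 cells, folds relative to a shift of 0.19 in the median of all genes) had less Cxcl3 at -2.39, Cxcl2 at -1.54 (5709 against 14529 CPM) and S100a9 at -1.04, although the tumour-promoting list as a whole was closer to level at -0.29 (2 higher, 4 lower, 6 within). The cAMP-responsive Crem was lower at -3.02 and the regulatory list at -0.91, with Arg2 at -1.38 and Socs3 at -1.17, while MHC class II genes were higher at 1.27 with Cd74 at 2.22 and H2-Aa at 1.44. RNA of DCs and macrophages is not excluded as a source of the MHC class II values. After NK depletion (76 against 111 cells) type I interferon genes of neutrophils stood at -1.09 (-0.58 with genes of 0 UMIs at their bound, Isg15 at -1.56) and tumour-promoting genes at -0.74 (1 higher, 8 lower, 3 within, Cxcl3 at -1.16, S100a8 at -1.06). Few cells and shallow depth limit these values.

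Monocytes and macrophages of Ptgs-/- tumours had more hypoxia and glycolysis RNA (median 0.53, 4 higher, 0 lower, 7 within, Egln3 at 1.02, Bnip3 at 0.86) and a mixed cholesterol list (-0.41), with the efflux pump Abcg1 at 1.09. The hypoxia list was lower again after NK depletion, at -0.35 with Eno1 at -0.96. The cluster TAM 3, with the hypoxia genes Ndrg1, Ero1l and Slc2a1 among its markers, made up 9.75% of the class in Ptgs+/+, 15.6% in Ptgs-/- and 9.68% in depleted libraries, the same rise and fall. Both comparisons share the Ptgs-/- library, so a high value in that library alone would give this order. Inside clusters the hypoxia list for Ptgs-/- over Ptgs+/+ tumours stood at 0.73 in TAM 1, 0.14 in TAM 3 and -0.70 in Monocytes 1, and after depletion at 0.14, 0.35 and -0.47. The type I interferon difference between Ptgs-/- and Ptgs+/+ tumours varied across clusters, at 1.68 in Monocytes 2, 0.83 in TAM 2, 0.32 in TAM 4 and 0.22 in the cluster Mono Mac, and the difference after depletion was -0.83 in Monocytes 2 and TAM 2, -0.12 in TAM 4 and 0.02 in Mono Mac.

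Compared with Ptgs+/+ tumours, NK-depleted Ptgs-/- tumours still had the T and NK list at 1.42 and tumour-promoting genes at -1.35 in CCR7+ DCs, with Ccl17 at 5.75 and Il1b at -2.95. In monocytes and macrophages type I interferon genes stood at 0.81, tumour-promoting genes at -1.08 and Cxcl3 at -4.23. In T cells type I interferon genes stood at -0.21, from 3 measured members.

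The list of genes that tissue dissociation induces was higher after NK depletion, at 0.56 in CCR7+ DCs (5 higher, 0 lower, 6 within, Dusp1 at 0.93, Junb at 0.87), 0.55 in cDC2s and 0.34 in cDC1s. It shares immediate-early regulation with Nr4a1 and other genes of the prostaglandin and cAMP list, so handling of the library remains open for the latter's higher value in cDC2s of depleted mice.

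In CT26 tumours NK cells were 15.0% of cells, T cells 8.53% and monocytes with macrophages 57.6%, and cDC1s were 37.3% and cDC2s 50.7% of conventional DCs. The 123 CT26 cells annotated as proliferating had Mki67 in 91.9% and Top2a in 87.8% of cells, and 13 of them held the mast cell and basophil protease Cpa3 (1893 against 28.7 CPM in other cells) and 13 held Mcpt8.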
